A study of Mus musculus with 12 samples.

How the data were processed

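RNA-seq and ATAC-seq were made from mouse 2-cell embryos cultured with IWR1-endo or DMSO. Per the labels' protocols, RNA-seq libraries came from 4 independent collections of 10 embryos per group with the SMART-Seq v4 kit, and ATAC-seq libraries from 2 independent collections of 100 embryos per group, amplified by 15 PCR cycles after which mitochondrial fragments were depleted with Cas9. Culture was in KSOM medium at 5% oxygen. The submitters' processing notes name the mm10 build, bcl2fastq, cutadapt 1.11, Trim Galore, STAR 2.5.1b, Bowtie2 2.2.6, featureCounts 1.5.0-p1, MACS2 and DESeq2, without a role or an order. Whether ATAC-seq reads were shifted for the transposase, how the regions were selected, and whether libraries were pooled for it is not given in the sources used here.

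The authors' deposited RNA-seq table gives raw counts per gene and library, without normalization per the file headers. FPKM values of all 8 libraries were computed here from the counts, the deposited gene length and the library's total count. Set against the FPKM values the authors deposited for the 4 DMSO libraries, the largest difference was 2.58e-10 FPKM. The deposited log2 fold changes and the deposited p-values, raw and adjusted, are the authors' DESeq2 comparison per the file title, and were used only as a comparison. No result given here uses a table of read statistics per library, because its IWR1 entries, numbered 5 to 8 like the count columns, could be assigned to the group only and the raw counts were kept as the only measure of such columns. The depth tiers were first set by that table and then set again by total counts, with the same libraries in each. The authors' ATAC-seq lists give chromosome, start and end of regions higher or lower in IWR1, with no fold, score or value per library, so the depth behind them is unknown. Whether their coordinates count from 0 or 1 is not stated, and they are printed as deposited.

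The table has 24918 gene entries and 0 entries that name no gene. Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, which matched 24815 entries (99.6%) by gene ID. That table gives no strand, so the transcription start sites planned for the ATAC-seq comparisons were replaced by the distance to either boundary of a gene. The IWR1 columns are numbered 5 to 8 while the labels number the samples 1 to 4, so these columns were assigned to the group and not to single samples. For that reason the raw counts were the only measure used for IWR1, and 12 other columns of per-library values were not used here.

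Genes were filtered with filterByExpr, leaving 14994; 4838 genes had no count in any library. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts with TMM scaling (trimmed mean of M-values), treatment as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Before the data were examined, 27 gene lists with 972 entries were fixed. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 26 lists tested, camera called 3 up and 12 down; with an estimated correlation 0 were called after adjustment (7 at an unadjusted p under 0.05), and fry called 23, where fry asks whether the genes of a list move on balance and does not compare them with other genes. Group values of library statistics were compared by an exact permutation test over all regroupings.

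Regions were compared by Fisher's exact test on the share within 1 kb of a boundary of the 21887 annotated protein-coding genes, and widths by a permutation test with 100000 resamples. Random placement kept each region's width and chromosome, within the span of annotated genes, without leaving out unmappable sequence. For the join with RNA-seq, the 14937 tested genes with 1 locus on the listed chromosomes were used, with a region within 10 kb of a boundary, and the median log2 fold change was set against 10000 random lists matched on mean FPKM in 20 strata. SciPy 1.17.1, statsmodels 0.14.6, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used under Python 3.11.15.

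Named genes followed a rule written before the data were examined. They were the 5 largest rises and 5 largest falls among called genes with all 4 IWR1 libraries on the same side of all 4 DMSO libraries, a mean of at least 5 FPKM and a named symbol, then Tnks, Tnks2, Rnf146, Axin1, Axin2, Ctnnb1 and Myc, and up to 3 members of each list by smallest adjusted p. To these came the 3 widest regions of each ATAC-seq list, and up to 5 genes per direction by smallest adjusted p with a region changed in the same direction within 10 kb. Tcl1, Dppa3 and members named to account for a small count were chosen after their values were seen.

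The edgeR test was tested on simulated counts for the 14994 genes of the IWR1 against DMSO comparison. With 200 genes changed 2-fold it recovered 4 with 0 false calls, and with 200 genes changed 4-fold it recovered 98 with 7 false calls. DESeq2 on the same simulated counts recovered 43 with 23 false calls at 2-fold and 118 with 45 false calls at 4-fold. At 4-fold, 6.67% of edgeR's calls were false, also above the threshold of 0.05, and the calls of DESeq2 were looser still in this simulation. The counts were simulated with dispersions estimated by edgeR, which may favour edgeR. These shares hold for a simulation with 200 changed genes only and do not give the recovery in the real comparison, where 5864 of 7297 called genes changed at least 2-fold and the others less. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. The lowest and highest total counts were 16606155 and 49672143. The smallest chi-square per degree of freedom between libraries of a group was 26.6, so no libraries agreed within sampling noise. Libraries with a total count of at most 20395940 (DMSO 1 and 2, IWR1 5 and 7) are called shallow and the others deep; the labels give no batch.

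Alternatives covered the filter on low counts, the scaling, robust edgeR, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1, each library left out in turn, stricter thresholds, the list test, and the window and calls of the ATAC-seq comparisons.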

Results

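The series examined transcription and open chromatin in mouse 2-cell embryos cultured with an inhibitor of tankyrase, a poly-ADP-ribosyltransferase that promotes degradation of the scaffold protein Axin. Embryos from NSA(CF-1) females mated to B6SJLF1/J males were recovered at the pronuclear stage, 16 to 20 h after injection of human chorionic gonadotropin. Culture medium held either 50 µM IWR1-endo, a tankyrase inhibitor called IWR1 below, or its solvent DMSO, and embryos were collected 46 h after the injection. RNA-seq was made from 4 independent collections of 10 embryos per group, and ATAC-seq, which maps open chromatin with a transposase, from 2 independent collections of 100 embryos per group. The RNA-seq table numbers the DMSO libraries 1 to 4 and the IWR1 libraries 5 to 8, and these numbers are used below. Total gene counts ranged from 16606155 to 49672143 in the DMSO libraries and from 17963977 to 32931800 in the IWR1 libraries.

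Log-scale expression correlated across genes at 0.897 to 0.934 between libraries of a group and at 0.707 to 0.842 between groups. Genes are not independent replicates, so these values only describe the libraries. The leading principal component held 57.7% of the variance and had all 4 DMSO libraries on the negative side and all 4 IWR1 libraries on the positive side. More genes had at least 1 count in IWR1, 17194 ± 282 (SD, n = 4), than in DMSO, 15970 ± 320 (SD, n = 4; exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 libraries allow). Thinned to 16606155 counts each, IWR1 libraries had 17066 ± 289 (SD, n = 4) such genes and DMSO libraries 15768 ± 436 (SD, n = 4; exact permutation test, two-sided, p = 0.0286). The 10 most abundant genes of a library took 12.9% ± 1.20 (SD, n = 4) of the counts in IWR1 and 6.43% ± 0.473 (SD, n = 4) in DMSO (exact permutation test, two-sided, p = 0.0286). Among these abundant genes, the oocyte gene Btg4, an adaptor of mRNA deadenylation, took 1.34% ± 0.279 (SD, n = 4) of the counts in IWR1 and 0.191% ± 0.0791 (SD, n = 4) in DMSO. The oocyte transcript Tcl1 took 1.86% ± 0.149 (SD, n = 4) in IWR1 and 0.432% ± 0.151 (SD, n = 4) in DMSO.

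The comparison of IWR1 with DMSO asked which transcripts differ when tankyrase is inhibited. Most tested genes on the lists of ribosomal proteins, ribosome biogenesis, the proteasome and the spliceosome were lower in IWR1 embryos, while more listed oocyte and early 2-cell genes rose than fell. These list calls rest on camera's preset correlation between genes, and with an estimated correlation none of the lists was called. Of 14994 genes tested, 3494 were higher and 3803 lower in IWR1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p threshold 0.05). Which direction held more genes depended on scaling and test: 3056 were higher and 4132 lower with median-centred libraries, 4056 and 3246 with library totals alone, and 4114 and 3904 by DESeq2. The median log2 fold change of all genes tested was 0.17 under TMM scaling, 0.04 with median-centred libraries and 0.34 with library totals alone, and changes are to be read against that shift. Scaled counts give abundance relative to the rest of a library. Rises and falls here are therefore relative, and amounts per embryo are not known. The change went with expression level: the median log2 fold change was 0.70 in the 1500 genes with the lowest mean FPKM and -0.66 in the 1500 with the highest. Of the latter, 807 were called lower and 411 higher. Only the ribosomal protein and ribosome biogenesis lists were set against genes matched on mean FPKM. For the other lists, expression level as a source of the change was not tested. Fewer genes were called among the 4 shallow libraries alone (1900 higher, 2112 lower) and among the 4 deep ones alone (2166 higher, 2789 lower).

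Among named genes with a mean of at least 5 FPKM, the prolactin family gene Prl7b1 (gene ID 75596, mm10 chromosome 13, 27601812 to 27610582) fell from 13.4 ± 6.79 FPKM (SD, n = 4) in DMSO to no count in the 4 IWR1 libraries. Its 2008 counts in DMSO make it at least 490.4-fold lower in IWR1, against a floor of 3 counts over the group (edgeR adjusted p = 2.76e-05). Fez1 (gene ID 235180, chromosome 9, 36821398 to 36878926), known from axon outgrowth, fell by 5.37 on the log2 scale (SE 0.60, adjusted p = 3.11e-05 by the same edgeR test). Zfp934 (gene ID 77117, chromosome 13, 62516795 to 62579321), a zinc finger gene, fell by 4.76 (SE 0.55, edgeR adjusted p = 3.58e-05). Surf2 (gene ID 20931, chromosome 2, 26916372 to 26920187) fell by 5.28 (SE 0.48), and the nucleotidase gene Nt5c (gene ID 50773, chromosome 11, 115490420 to 115492070) fell by 4.51 (SE 0.60). The log2 fold change of Surf2 was -5.90 without IWR1 library 7 and that of Zfp934 was -4.10 without DMSO library 3. The Surf2 model overlaps Surf1 and Surf4 and that of Nt5c overlaps Armc7, so their counts are uncertain without strand.

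The largest rises by the same rule were in genes with low values in DMSO. Mir196b (gene ID 723820, chromosome 6, 52230081 to 52230165), a microRNA gene inside a long non-coding gene model, rose by 7.30 on the log2 scale (SE 1.37), from 0.177 ± 0.354 to 27.9 ± 21.7 FPKM (SD, n = 4). That long model, Gm52902, was not counted, so the reads could come from it and need not show the microRNA. As the Mir196b model has 85 bases, these FPKM values rest on 29 to 140 counts per IWR1 library. Rnase4 (gene ID 58809, chromosome 14, 51091077 to 51106151), whose model overlaps Ang and is uncertain for that reason, rose by 6.53 (SE 0.97, edgeR adjusted p = 0.000175). The chemokine gene Cxcl1 (gene ID 14825, chromosome 5, 90891245 to 90893121) rose by 6.18 (SE 1.33) and the osteopontin gene Spp1 (gene ID 20750, chromosome 5, 104435111 to 104441053) by 6.05 (SE 1.14). Prr15 (gene ID 78004, chromosome 6, 54326756 to 54343436) rose by 5.58 (SE 0.87), from 0.269 ± 0.380 to 11.8 ± 3.51 FPKM (SD, n = 4). The adjusted p of these 5 genes lay between 0.000175 and 0.00225 (edgeR, Benjamini-Hochberg). The Prr15 model overlaps 9130019P16Rik, so its counts are uncertain. Rnase4 and Prr15 had means of 0.186 and 0.269 FPKM in DMSO, so their folds rest on few counts there. All DMSO counts of Mir196b and Cxcl1 came from DMSO library 1 (1 and 14 counts), and without it they were at least 95.3-fold and 417.6-fold higher in IWR1, against a floor of 3 counts over the remaining DMSO libraries. The log2 fold change of Mir196b was 6.59 without IWR1 library 8, which held 140 of its counts, and that of Cxcl1 was 5.30 without IWR1 library 5, which held 485. Without DMSO library 2 that of Spp1 was 8.51, without DMSO library 4 that of Rnase4 was 8.94, and without DMSO library 1 that of Prr15 was 7.27, so the sizes of these rises depend on single libraries. Each call stayed without any 1 library, and that of Mir196b was lost among the shallow libraries alone (edgeR adjusted p = 0.0566).

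The genes closest to the inhibitor's target moved in different directions. Ctnnb1 (gene ID 12387, chromosome 9, 120933400 to 120960507), which encodes beta-catenin and overlaps Mir7090, fell by 1.68 on the log2 scale (SE 0.25), from 29.0 ± 7.47 to 10.4 ± 2.36 FPKM (SD, n = 4; edgeR adjusted p = 0.000196). Myc, a transcription factor gene regulated by beta-catenin in many cells, fell by 2.21 (SE 0.52), from 3.83 ± 1.40 to 0.936 ± 0.516 FPKM (SD, n = 4; edgeR adjusted p = 0.00383). Axin2 (gene ID 12006, chromosome 11, 108917828 to 108950783), a scaffold of the beta-catenin destruction complex and a common Wnt target, rose by 0.77 (SE 0.24), from 3.16 ± 0.734 to 6.09 ± 0.607 FPKM (SD, n = 4; edgeR adjusted p = 0.0173). Rnf146, the ubiquitin ligase that reads tankyrase's mark, rose by 0.86 (SE 0.29), from 4.51 ± 1.66 to 9.21 ± 2.66 FPKM (SD, n = 4; edgeR adjusted p = 0.0282); its model overlaps Echdc1. Both calls were fragile: Axin2 had an adjusted p of 0.0523 without DMSO library 2, and Rnf146 had 0.0774 without DMSO library 1, 0.0565 without DMSO library 4, 0.0641 without IWR1 library 5 and 0.0956 without IWR1 library 6 (edgeR). Among the shallow libraries alone the adjusted p was 0.258 for Axin2 and 0.214 for Rnf146, and among the deep libraries alone 0.0817 and 0.104 (edgeR). The call for Myc was lost among the shallow libraries alone (edgeR adjusted p = 0.0651). The tankyrase genes did not pass the test, with log2 fold changes of -0.31 (SE 0.27, edgeR adjusted p = 0.363) for Tnks and 0.02 (SE 0.23, adjusted p = 0.953) for Tnks2, and Axin1 had -0.25 (SE 0.21, adjusted p = 0.351).

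Of the 28 tested genes of the tankyrase and beta-catenin machinery, 9 rose and 4 fell, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.317). The genes of the beta-TrCP ubiquitin ligases, Fbxw11 and Btrc, each fell by 1.38 (SE 0.22 and 0.26). Among 19 tested Wnt/beta-catenin targets, 7 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.199). Those that rose included the Wnt receptor partner gene Lgr5 (log2 fold change 2.75, SE 0.54), the Wnt inhibitor gene Nkd1 (1.80, SE 0.35) and the transcription factor gene Ascl2 (3.40, SE 0.68). Lgr5 lost its call among the shallow libraries alone (edgeR adjusted p = 0.0919). Ascl2 lost its call among the deep libraries alone (edgeR adjusted p = 0.0589), and its log2 fold change was 4.33 without DMSO library 3.

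Ribosomal protein genes fell together: 76 of 77 passed the test downward, 77 of 77 when adjusted over the list alone, with a median log2 fold change of -2.19 (camera adjusted p = 8.66e-25, adjusted p = 0.205 with an estimated correlation). Rps6 fell from 210 ± 21.4 to 35.6 ± 9.67 FPKM (SD, n = 4; edgeR adjusted p = 8.38e-06) and Rps24 from 639 ± 96.1 to 134 ± 26.6 FPKM (SD, n = 4). All 60 ribosome biogenesis genes fell, 60 when adjusted over the list alone, with a median of -1.81 (camera adjusted p = 1.80e-18, adjusted p = 0.175 with an estimated correlation). Ddx21, a nucleolar RNA helicase gene, fell by 2.51 (SE 0.20) and the ribosome assembly gene Imp3 by 2.77 (SE 0.24). Of 56 Myc targets, many of them nucleolar, 39 fell and 6 rose, 40 and 6 adjusted over the list alone (median -1.30, camera adjusted p = 5.41e-07, adjusted p = 0.203 with an estimated correlation). Gnl3, which encodes nucleostemin, fell by 2.18 (SE 0.21). The Myc list shares members with the ribosome biogenesis list, among them Gnl3, Imp4 and Ppan, so the 2 calls are not independent. Some of the lists below also share members.

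**Figure D1:**
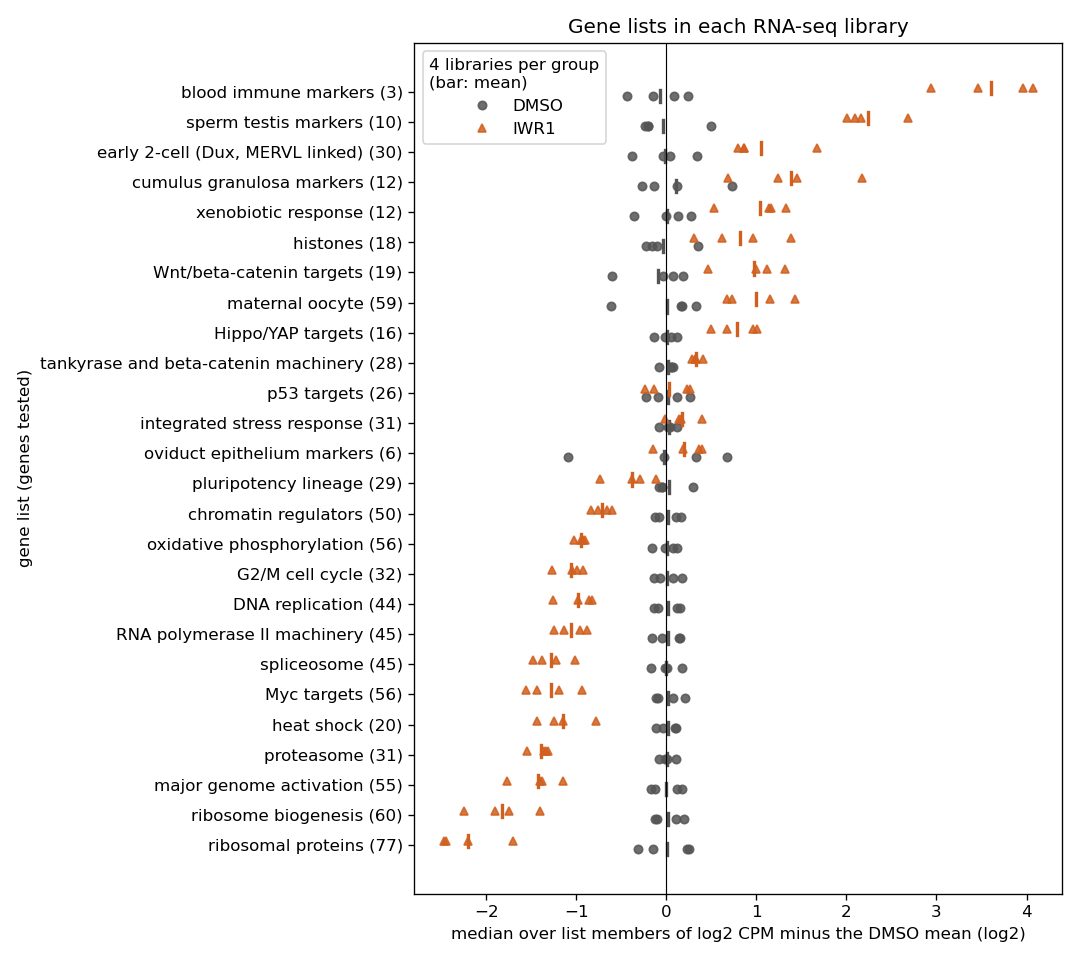
Median over the members of each gene list of the log2 CPM minus the mean of the DMSO libraries (horizontal axis, log2), for the 4 DMSO libraries (circles) and the 4 IWR1 libraries (triangles), with the group mean as a bar and the number of genes tested in brackets. Ribosomal proteins lie at the bottom, with a median log2 fold change of -2.19 over 77 genes. The blood and immune markers lie at the top, with 3.58 over the 3 of 13 genes that passed the count filter.

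Genes that rise in the major wave of embryonic genome activation were lower in IWR1: 46 of 55 fell, 46 adjusted over the list alone, and Actb alone rose (median -1.44, camera adjusted p = 2.85e-11, adjusted p = 0.175 with an estimated correlation). Umps, of pyrimidine synthesis, fell by 3.39 (SE 0.21) and the pluripotency-associated gene Dppa2 by 2.70 (SE 0.23). Of 31 proteasome genes 25 fell and 1 rose, 25 and 2 adjusted over the list alone (median -1.42, camera adjusted p = 2.78e-08, adjusted p = 0.175 with an estimated correlation), with Psma6 falling from 585 ± 17.2 to 57.5 ± 15.0 FPKM (SD, n = 4). Of 45 spliceosome genes 33 fell and 0 rose, the same adjusted over the list alone (median -1.24, camera adjusted p = 3.75e-10, adjusted p = 0.175 with an estimated correlation), among them the core protein gene Snrpd1, which fell by 2.59 (SE 0.20). Of 45 genes of the RNA polymerase II machinery 31 fell and 6 rose, also when adjusted over the list alone (median -1.05, camera adjusted p = 2.65e-06, adjusted p = 0.193 with an estimated correlation). The Mediator gene Med17 fell by 3.53 (SE 0.26) and Tbp, which encodes the TATA-binding protein, by 2.28 (SE 0.18).

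Chromatin regulators fell in 27 of 50 cases and rose in 2, 28 and 2 adjusted over the list alone (median -0.68, camera adjusted p = 0.000403, adjusted p = 0.175 with an estimated correlation), and the remodeller gene Smarca5 fell by 1.83 (SE 0.20). Of 44 DNA replication genes 31 fell and 3 rose, also adjusted over the list alone (median -0.97, camera adjusted p = 4.27e-06, adjusted p = 0.175 with an estimated correlation), including the replication initiation gene Gins3, which fell by 3.86 (SE 0.36). Of 32 G2/M genes 21 fell and 2 rose, also adjusted over the list alone (median -0.91, camera adjusted p = 9.85e-05, adjusted p = 0.270 with an estimated correlation), including Cdk1, which fell by 1.88 (SE 0.18). Of 56 nuclear genes of oxidative phosphorylation 36 fell and 7 rose, 38 and 7 adjusted over the list alone (median -0.88, camera adjusted p = 4.32e-06, adjusted p = 0.175 with an estimated correlation), with the complex I gene Ndufb7 falling by 3.46 (SE 0.27). Heat shock genes fell in 12 of 20 cases and rose in 2, also adjusted over the list alone (median -1.40, camera adjusted p = 0.0101, adjusted p = 0.175 with an estimated correlation). Among them Hspa8 fell by 1.90 (SE 0.22). The heat shock list was not called when genes under a mean of 5 FPKM were left out (camera adjusted p = 0.194). None of the lists in this paragraph was set against genes of like expression. Of the 1500 genes with the highest mean FPKM, 807 fell and 411 rose.

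Maternal oocyte transcripts were higher in IWR1 relative to other transcripts: 32 of 59 rose and 5 fell, 35 and 5 adjusted over the list alone (median 0.92, camera adjusted p = 0.000106, adjusted p = 0.404 with an estimated correlation). A larger share of the library need not mean more copies per embryo. The histone chaperone gene Npm2 rose by 2.05 (SE 0.22) and Btg4 by 2.66 (SE 0.32, edgeR adjusted p = 4.54e-05), and the mRNA-binding protein gene Ybx2 also rose (edgeR adjusted p = 3.56e-05). The 5 that fell were Ccnb1, Ccnb1ip1, Dppa3, Zar1l and Zp3, and Dppa3, a maternal factor, fell by 1.09 (SE 0.22). Early 2-cell genes linked to Dux and MERVL were also higher, with 16 of 30 up and 1 down, as adjusted over the list alone (median 1.09, camera adjusted p = 0.00168, adjusted p = 0.404 with an estimated correlation). Zscan4c rose from 7.43 ± 1.12 to 89.0 ± 14.9 FPKM and Zscan4f from 8.20 ± 1.98 to 128 ± 20.5 FPKM (SD, n = 4; edgeR adjusted p = 3.69e-06 and 4.34e-06). The Zscan4 genes are near-identical copies whose reads the counting could have split, so the values of each copy are uncertain.

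**Figure D2:**
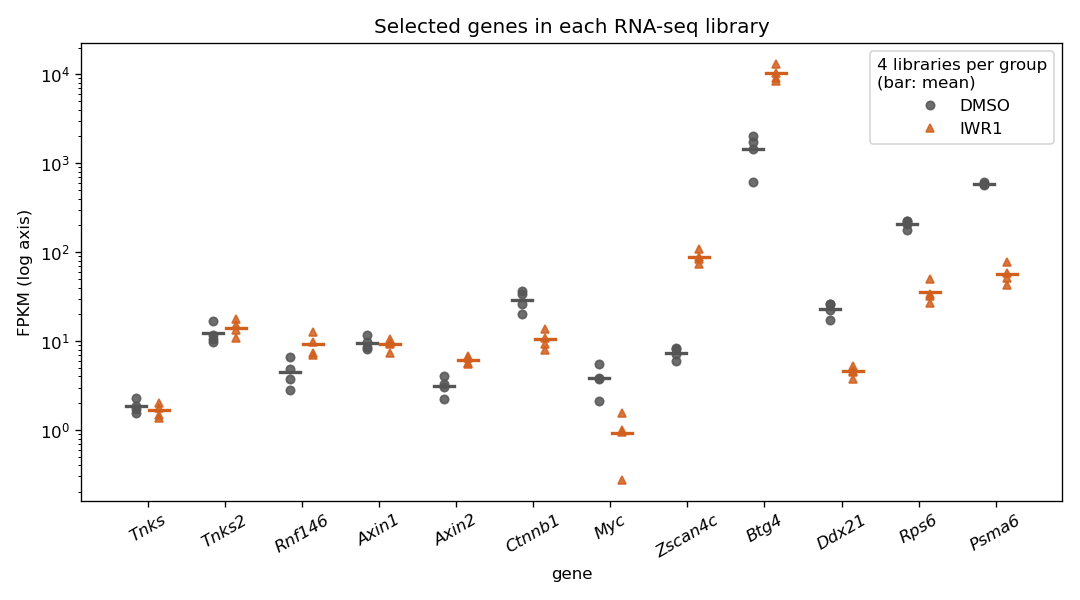
FPKM (log axis) of 12 genes in the 4 DMSO libraries (circles) and the 4 IWR1 libraries (triangles), with the group mean as a bar. Psma6 falls from a mean of 585 to 57.5 FPKM and Zscan4c rises from 7.43 to 89.0 FPKM, while the groups of Tnks and of Tnks2 overlap.

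Pluripotency and lineage genes had 5 up and 12 down of 29 (camera adjusted p = 0.317), with Tfap2c falling by 2.35 (SE 0.26) and Krt18 rising by 1.81 (SE 0.30). Histone genes had 5 up and 3 down of 18, 4 and 3 adjusted over the list alone (camera adjusted p = 0.201). Among p53 targets 5 rose and 8 fell of 26 (camera adjusted p = 0.771), with a positive median of 0.25 and mean of 0.01 against a downward test, and among genes of the integrated stress response 6 rose and 9 fell of 31 (camera adjusted p = 0.977; median 0.09 and mean 0.12, test downward). In the stress list Nupr1 rose by 2.62 (SE 0.29) while Ppp1r15a fell by 2.46 (SE 0.25). Hippo/YAP targets had 5 up and 3 down of 16, 5 and 4 adjusted over the list alone (camera adjusted p = 0.286), and xenobiotic response genes 5 up and 1 down of 12 (camera adjusted p = 0.0783; called without DMSO library 1 or 2 or IWR1 library 7, at 0.0264, 0.0473 and 0.0217, with no filter on low counts, at 0.0247, and among the deep libraries alone, at 0.0170). None of these lists was called in the main test. Adjusted over the list alone, the pluripotency, p53, stress and xenobiotic counts were the same. The list of mitochondrially encoded genes had 0 members in the table.

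Markers of other cell types were measured beside these groups. Of 13 blood and immune markers in the table, only 3 passed the count filter, so these do not stand for the whole list. All 3 rose, 3 also when adjusted over the list alone (median 3.58, camera adjusted p = 0.0200, adjusted p = 0.175 with an estimated correlation). With no filter on low counts the median was 1.61 and the camera adjusted p = 0.0577. Lyz2, the lysozyme gene of myeloid cells, rose by 3.76 on the log2 scale (SE 0.45), the invariant chain gene Cd74 from 1.58 ± 1.43 to 20.7 ± 2.85 FPKM (SD, n = 4; log2 fold change 3.58, and 4.26 without DMSO library 2) and the macrophage gene Cd68 from 3.30 ± 0.543 to 9.32 ± 1.93 FPKM (SD, n = 4). Cd68 lost its call among the shallow and among the deep libraries alone (edgeR adjusted p = 0.0659 and 0.0938). Sperm and testis markers had 4 up and 1 down of 10 (camera adjusted p = 0.0533; called without DMSO library 1, 2 or 3, at 0.0332, 0.0473 and 0.0412, with median-centred libraries, at 0.0420, with no filter on low counts, at 0.0290, and among the shallow libraries alone, at 0.0229), with the protamine gene Prm2 at 1.18 ± 0.641 and 12.8 ± 3.86 FPKM (SD, n = 4). Cumulus and granulosa markers had 2 up and 1 down of 12, 1 and 1 adjusted over the list alone (camera adjusted p = 0.271), and oviduct markers 1 up and 2 down of 6 (camera adjusted p = 0.837; median -0.05 and downward test against a mean of 0.58). Adjusted over the list alone, the sperm and oviduct counts were the same. These 3 lists had 15 sperm, 24 cumulus and 12 oviduct genes in the table, and the rest did not pass the count filter.

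In the authors' deposited table, 4503 genes were higher and 3969 lower at an adjusted p under 0.05. The edgeR fit and the authors' deposited table shared 7262 genes called in the same direction and 0 in opposite directions. Across 14950 genes with a value in both, the log2 fold changes correlated at 1.00. Both rest on the same counts, so this compares methods and not experiments.

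The ATAC-seq comparison asked which open chromatin regions differ between IWR1 and DMSO. The authors' deposited lists hold 2345 regions higher and 1400 regions lower in IWR1, and no base was shared between the lists. Regions higher in IWR1 lay near gene boundaries: 43.2% were within 1 kb of the start or end of a protein-coding gene, against 5.64% of those lower in IWR1 (odds ratio 12.7, 95% interval 9.99 to 16.2, Fisher's exact test, two-sided, p = 5.90e-155). The odds ratio was 4.55 within 5 kb, 3.13 within 10 kb and 7.06 within 1 kb of a boundary of any annotated gene. Placed at random on the same chromosomes 100 times, regions of the same widths gave 4.01% to 6.48% for the higher list and 3.71% to 6.14% for the lower list. A protein-coding gene was overlapped by 66.4% of the higher and 50.9% of the lower regions, against 41.6% and 41.1% on average at random. Regions are not independent replicates, and the lists give no value per library, so these tests compare the deposited lists only.

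The median width was 1098 bases in the higher and 1000 bases in the lower list, and 42.6% and 63.3% of the regions were exactly 1000 bases by subtraction of the coordinates (mean difference of log2 width 0.07, permutation test, two-sided, p = 2e-05, the smallest that 100000 resamples give). The widest higher regions were on mm10 chromosome Y, 90763166 to 90785464, over the pseudogene Mid1-ps1, on chromosome 13, 119595251 to 119603717, within Tmem267, and on chromosome 1, 5108926 to 5114681, within Atp6v1h. The widest lower regions were on chromosome 9, 2999633 to 3038620, with no annotated gene, on chromosome 11, 60634213 to 60643252, over Gm12625, and on chromosome X, 94968884 to 94977689, with no annotated gene. The region on chromosome 9 was 38987 bases wide, against 9039 for the next lower region. Whether reads map uniquely in these widest regions was not examined, so a mapping artifact cannot be told apart from a change in open chromatin there.

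Genes near regions lower in IWR1 were more often lower in RNA-seq, and genes near regions higher in IWR1 more often higher. Of 670 tested genes with a lower region within 10 kb of a gene boundary, 42.7% fell, against 24.6% of other genes (odds ratio 2.29, 95% interval 1.95 to 2.68, Fisher's exact test, two-sided, p = 1.52e-23, adjusted p = 6.09e-23 over 4 tests). In that set 13.9% rose, against 23.7% (odds ratio 0.518, Fisher's exact test, adjusted p = 9.58e-10). Of 2024 genes near a higher region, 27.1% rose, against 22.7% (odds ratio 1.27, 95% interval 1.14 to 1.41, Fisher's exact test, adjusted p = 1.49e-05), and 18.2% fell, against 26.5% (odds ratio 0.619, Fisher's exact test, adjusted p = 7.01e-16). In a window of 50 kb, which includes the genes within 10 kb, risen genes were not in excess near higher regions (odds ratio 1.00, Fisher's exact test, p = 1.0). Fallen genes were still fewer there (odds ratio 0.884, Fisher's exact test, p = 0.00365). The median log2 fold change was -0.60 near lower regions, where 10000 random gene lists matched on mean FPKM gave -0.23 to 0.37, and 0.42 near higher regions, where they gave -0.05 to 0.29. Genes near lower regions were more expressed, with a median of the mean FPKM of 8.30 against 4.11 in other genes. Pooled within 20 strata of mean FPKM, the odds ratio of a fall near lower regions was 1.91 (95% interval 1.61 to 2.28). That of a rise near higher regions was 1.28 (95% interval 1.15 to 1.42). Genes are not replicates, and distance alone linked them to regions.

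Among risen genes with a higher region nearby, Zscan4c (chromosome 7, 11005745 to 11010547) had the region 11005173 to 11006173 across its boundary and Zscan4f (chromosome 7, 11397915 to 11402318) the region 11397081 to 11398197. The sterol transport gene Stard4 (chromosome 18, 33199138 to 33213862), which rose by 2.70 (SE 0.21), had the region 33213124 to 33214510 across its boundary. The unnamed models Gm20767 and 2810408I11Rik rose by 2.14 (SE 0.17) and 2.59 (SE 0.22), with regions 205 and 5254 bases from a boundary. Among fallen genes with a lower region nearby, Ddx21 (chromosome 10, 62580247 to 62602298) had the region 62601884 to 62604880 across its boundary. The meiotic checkpoint gene Trip13 fell by 2.88 (SE 0.20) with a region 1014 bases from a boundary, the ribosome recycling gene Abce1 by 2.75 (SE 0.20) with a region 2004 bases from a boundary, Sarnp by 2.73 (SE 0.21) with a region 516 bases from a boundary and the peroxiredoxin gene Prdx3 by 2.91 (SE 0.23) with a region 2996 bases from a boundary. None of Tnks, Tnks2, Rnf146, Axin1, Axin2, Ctnnb1 and Myc had a deposited region of either list within 10 kb of a boundary.

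**Figure D3:**
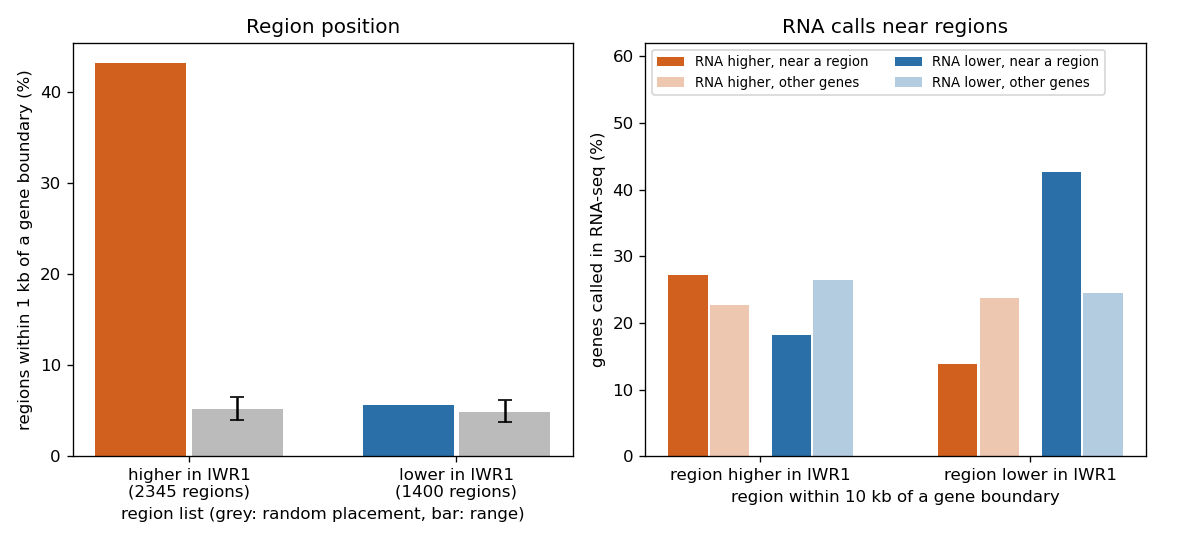
Left: percent of the 2345 regions higher and 1400 regions lower in IWR1 within 1 kb of a protein-coding gene boundary (coloured bars, 43.2% and 5.64%), beside the mean of 100 random placements (grey bars, with their range). Right: percent of genes called higher (orange) or lower (blue) in RNA-seq with a region of each list within 10 kb of a boundary (full colour) and among all other tested genes (pale), such as 42.7% against 24.6% for fallen genes near lower regions.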

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

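The tests of scaling and of depth at equal totals were chosen only after the result was seen; the other tests below were written down before theirs, those on region position after the shares of the lists were known.

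In groups of 4 libraries, a library was singled out when its gap to the nearest other was large against the group's range by Dixon's test at 95%, which chance gives in about 1 in 20 groups; 256 groups were examined and 23 values stood apart. In DMSO library 1, Mir196b was at 0.708 FPKM and Cxcl1 at 0.888 FPKM, where the other 3 DMSO libraries had 0. In DMSO library 2, Psma6 was at 610.4 FPKM. In DMSO library 4, Rpl15 was at 107 FPKM, Ei24 at 63.5, Dnaja1 at 71.5, Ndufs8 at 219 and Tnfaip6 at 3.91 FPKM, each above the other DMSO libraries. In IWR1 library 5, Dppa2 was low at 54.3 FPKM, Tppp3 low at 9.68, Trip13 low at 6.46 and 2810408I11Rik high at 1168 FPKM. In IWR1 library 6, Btrc was at 4.94 FPKM, Ybx2 at 40.4, Med17 at 3.54 and Prdx3 at 9.67 FPKM, each above the other IWR1 libraries. In IWR1 library 7, Surf2 was high at 3.45 and Zfp934 low at 0.482 FPKM, and in IWR1 library 8 Ei24 was low at 14.9 FPKM. Of list medians, relative to the DMSO mean, the tankyrase and beta-catenin machinery was at -0.081 in DMSO library 2, the early 2-cell genes at 1.68 in IWR1 library 7, against 0.79 to 0.87 in the other IWR1 libraries, the pluripotency genes at 0.30 in DMSO library 4 and the sperm markers at 0.50 in DMSO library 3.

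The 7297 changed genes were set against every split of the 8 libraries into 4 and 4. Only the real split, 1 of 35, gave as many, and the highest other split gave 0 by edgeR after adjustment (1304 at an unadjusted p under 0.05, against 8245 in the real split). Chance assignment of the libraries would rank the real split highest in 1 of 35 cases, the smallest share that 4 against 4 libraries allow. That argues against chance assignment at this share only. It does not address a difference in collection or handling that goes with treatment. The other splits put IWR1 and DMSO libraries together, where a treatment difference would enter the spread, so their 0 calls do not measure how many calls chance gives.

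Ribosomal protein and ribosome biogenesis genes were lower in IWR1, with a median log2 fold change of -2.00 over 137 genes. Over the scalings run, the highest median was -1.82, with library totals alone. Random lists of other genes matched on length and mean FPKM reached a median of -0.99 at the lowest of 10000. Among shallow and among deep libraries alone the higher of the medians was -1.72. The scalings placed the median of all tested genes between 0.04 and 0.34, so none could have removed a fall of this size. That test shows only that the pattern held under each scaling run. The tests of gene length and depth argue against these as the whole cause. A response to IWR1 may account for the pattern, as a hypothesis found and tested on the same data. A difference in developmental timing between the groups was not tested.

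More genes were detected in IWR1 libraries, with Lyz2 and Cd74 among those higher. After thinning to equal totals the lowest IWR1 library still had 606 more detected genes than the highest DMSO library, which argues against depth. RNA of immune cells remains open. Over the IWR1 libraries, 15 genes abundant in macrophages had a median FPKM of 2.23% to 11.979% of that of Cd74. The bound set beforehand, 10%, was undercut in 3 of 4 libraries and exceeded in IWR1 library 8. This source could therefore not be excluded or shown. In the DMSO libraries, where Cd74 was low, the same share was 10.7% to 53.6%, above the bound throughout. The ratio therefore cannot tell immune RNA apart. Of the 15 genes, C1qb, Cd53, H2-Aa, H2-Ab1 and Laptm5 rose and Aif1 and Ctss fell, with H2-Aa at 110 FPKM in IWR1 and 11.9 FPKM in DMSO, while Ptprc, Tyrobp and C1qc were at 0 FPKM in both groups. These genes were named after their values were seen, and the embryos themselves may express some of them.

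Regions higher in IWR1 lay nearer to gene boundaries than regions lower in IWR1. Among regions of exactly 1000 bases the odds ratio was 15.2 (95% interval 10.6 to 21.9), and pooled within chromosomes it was 12.4 (95% interval 9.69 to 15.9), which argues against width and chromosome as the whole cause. How the authors selected the regions is not known here and may also shape the lists, which these tests leave open, as they do an effect of IWR1.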

How the results depend on the processing

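Library totals alone, thinning, the depth term, the shallow and deep subsets, limma with a pseudocount of 1, boundaries of any annotated gene, and the scalings and left-out libraries of the RNA join were chosen only after seeing the data. No paired analysis was possible because the IWR1 columns are numbered 5 to 8 and carry no replicate number shared with DMSO. Not run were a stricter threshold on the ATAC-seq regions, which carry no values, array weights and quantile normalization, planned for FPKM alone, and distances to start sites, replaced by gene boundaries.

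The count of 7297 changed genes stayed within 1.5 times under the other settings, except 4012 among the shallow libraries alone (1900 higher, 2112 lower); the deep libraries alone gave 2166 higher genes, and an adjusted p under 0.01 gave 2204. The subsets test fewer libraries and the last is a stricter threshold. The excess of lower over higher genes turned in several settings, among them library totals alone (4056 higher, 3246 lower), DESeq2 (4114, 3904) and limma with a pseudocount of 0.5 (3945, 3390). Leaving out each library gave 6539 to 6979 changed genes, 2940 to 3450 higher and 3438 to 3676 lower, and 0 calls changed sign. Called lists numbered 15, with 15 to 17 without a library, 0 with an estimated correlation and 23 with fry; the cause of the loss was not tested.

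The odds ratio for region position, 12.7 in the main test, was 16.4 within 0.5 kb, 17.8 for region midpoints, 7.06 with any annotated gene, 4.55 within 5 kb and 3.13 within 10 kb, in the same direction throughout. For genes near a higher region, the odds ratio of a rise was 1.00 at 50 kb, and the medians there were 0.21 near higher and -0.31 near lower regions. With the nearest gene at any distance, the odds ratio of a fall near lower regions was 1.48 and the median -0.13, against 1.54 for a rise near higher regions and a median of 0.59. The cause was not tested. Without a library, the odds ratios of a rise and a fall were 1.21 to 1.36 and 0.596 to 0.628 near higher regions, and 0.502 to 0.571 and 2.21 to 2.29 near lower regions; the medians were 0.40 to 0.45 and -0.62 to -0.53.

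Directions reversed only in results that did not pass the test, and the cause was not tested. The test of the integrated stress list turned upward with medians of 0.29 at a mean FPKM of at least 5, 0.14 with DESeq2 size factors, 0.13 with TMM factors from FPKM, 0.28 with library totals, 0.15 after thinning, 0.066 among shallow libraries, 0.17 without DMSO library 2 and 0.19 without IWR1 library 8 (range without a library 0.035 to 0.19). At a mean FPKM of at least 5 the tests of p53 targets (median 0.47), Hippo/YAP targets (-0.44) and cumulus markers (0.35) also turned, and without IWR1 library 8 that of p53 targets (0.35, range 0.12 to 0.35). The oviduct list turned without DMSO library 1 (0.76), 3 (0.79) or 4 (0.43) or IWR1 library 6 (1.07; range -0.054 to 1.07). Tnks2 turned to -0.13 with median-centred libraries and -0.16 among deep libraries, and below 0 without DMSO library 1 or 2 or IWR1 library 7 or 8 (range -0.11 to 0.26).

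Sperm markers were called with no filter (camera adjusted p = 0.0290), with median-centred libraries (0.0420), among shallow libraries (0.0229) and without DMSO library 1 (0.0332), 2 (0.0473) or 3 (0.0412). Xenobiotic genes were called with no filter (0.0247), among deep libraries (0.0170) and without DMSO library 1 (0.0264), 2 (0.0473) or IWR1 library 7 (0.0217). Tnfaip6 lost its call without any of 6 libraries (edgeR adjusted p 0.0547 to 0.0953). Of 2294 comparisons of 100 named genes, 2256 kept direction and side of the threshold, 32 lost the call and 6 reversed. In a simulation with 200 changed genes the test recovered 2% at 2-fold, and whether depth or spread sets this was not tested.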

Other observations

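No test in this part was chosen after its result was seen, except the relation of region share to gene density. Some families of genes sharing a symbol stem passed camera with its preset correlation, and with an estimated correlation each of those named here had an adjusted p = 0.436. Members shared with the fixed lists made up 17.6% of Krt, 9.43% of Eif, 7.89% of Ddx and none of Mrpl and Olfr. Of 47 mitochondrial ribosomal protein genes (Mrpl), 33 fell and 2 rose, with a median log2 fold change of -1.26 (camera adjusted p = 8.86e-06). Of 38 DEAD-box helicase genes (Ddx), 26 fell and 2 rose (median -1.24, camera adjusted p = 8.86e-06), and of 53 translation initiation factor genes (Eif) 34 fell and 6 rose (median -0.87, camera adjusted p = 2.05e-05). Olfactory receptor genes (Olfr) went the other way, with 20 of 54 up and 0 down (median 1.82, camera adjusted p = 0.000237), as did keratin genes (Krt), with 10 up and 1 down of 17 (median 1.81, camera adjusted p = 0.00635). Olfactory receptor genes are near-identical in part, so their counts are uncertain. Those tested are the ones that passed the count filter, and they do not stand for the whole family. Weakly expressed genes can pass that filter through the group where they are higher. Among the 1500 tested genes with the lowest mean FPKM, the median log2 fold change was 0.70, with 145 called higher and 26 lower. Over the other scalings run, the highest median was -1.08 for Mrpl, -1.05 for Ddx and -0.70 for Eif, and the lowest was 1.71 for Olfr and 1.69 for Krt.

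The hypothesis, written before its result, was that families other than the fixed lists changed together. Of 74 families of at least 15 tested genes, 8 passed camera with at least 80% of their called members in the same direction, so such families may have changed with the lists. The estimated correlation ended every call, and expression level was not tested for these families.

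The share of higher regions among both lists differed between chromosomes other than Y, from 38.1% on chromosome X to 83.4% on chromosome 15. Over these 20 chromosomes it went with the density of protein-coding genes (Pearson r = 0.507, permutation p = 0.023; Spearman rho = 0.448, permutation p = 0.049). Without chromosomes 7 and 11, farthest from the median density, the relation did not pass (r = 0.415, permutation p = 0.087, n = 18).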
